A study of Mus musculus with 54 samples.

How the data were processed

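ChIP-seq of H3K4me3, H3K27ac, H3K27me3, H3K9me2, total H3 and EGFP-BLIMP1 was labelled for 54 samples, of which 4 were inputs. Of these, 26 libraries had a file of window signal, and 4 position lists covered H3K4me3, H3K27ac and EGFP-BLIMP1 of day 2 and of day 6. Groups were taken from the labels as mark and cell type, with 2 libraries each. The submitters' processing notes name Bowtie 0.12.9, SAMtools 0.1.18, Picard 1.85 and MACS 1.4.2 and the build mm9, without saying which tool made which file. Read filters, the control used for the signal and the peak thresholds were not given in the sources used here.

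The signal in each window file was made by the authors as a relative level per 2-kb window at steps of 1 kb, and was deposited on a linear scale. The authors' formula for this signal is not stated. The mean over all windows was nearly equal in both libraries of a cell type and differed between cell types, while that of H3 was about 1 in each library. A scaling per cell type would give such means, but how the authors scaled the signal could not be tested. The position lists were deposited by the authors as positions of 1 bp without height, score or p, and those of H3K4me3 and H3K27ac combine all cell types. Depth per sample is unknown, since these are not counts, so the precision rests on the spread between 2 libraries.

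H3K27me3 files held 2654924 windows and those of H3K9me2 and H3 2542807. Windows at 0 in each library of the mark (139661, 28127 and 31515 windows for H3K27me3, H3K9me2 and H3) hold no information on change. H3K9me2 and H3 signal around H3K4me3 positions was lowest 2 kb downstream of them on each of 20 chromosomes with positions, and the pattern of windows at 0 matched that of H3K27me3 best at the same shift on 21 chromosomes (lowest correlation 0.745 for H3K9me2 and 0.736 for H3). These windows were therefore placed 2 kb upstream of their listed coordinates wherever they were joined with positions or with H3K27me3 regions, a choice made after the data were seen. The 20-kb bins and printed coordinates of H3K9me2 and H3 regions stayed as listed.

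Every second window was kept so that windows do not overlap. H3K27me3 was tested in the 10% of these windows with the highest mean over all libraries, and H3K9me2 and H3 in 20-kb bins with at least 5 windows. Tests of groups of windows within the top 10% used the same filter for each mark. It counts the libraries compared, so windows low in some cell types pass it mainly where others are high. Differences within it may therefore partly follow from the filter. Values were log2(signal + pseudocount), with a pseudocount of 0.0407 for H3K27me3, 0.123 for H3K9me2 and 0.615 for H3, the 10th percentile of the non-zero values of the mark, which draws changes between low values toward 0. For H3, with a median of 0.992 in ESC, it draws changes at usual levels toward 0 as well. All libraries of a mark were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust), and a call needed a Benjamini-Hochberg adjusted p under 0.05. The residual SD was 0.224, 0.143 and 0.0550 for H3K27me3, H3K9me2 and H3. The comparisons were EpiLC with ESC, each day 2 type with EpiLC, d2PGCLC with d2LIF_Ag, and d6PGCLC with d2PGCLC and with ESC, and those that share a group are not independent. Groups of windows at positions and on chromosome X were tested with camera in limma with a preset correlation of 0.01, and again with the correlation estimated from the data. Differences of a group are the median log2 change of its windows minus that of all windows. Levels relative to the library mean were computed after leaving out windows with a signal over 100. For groups of windows and for chromosomes this mean left out windows at 0 in each library of the mark. For profiles around positions, and for counts of positions with high H3K27me3, it was taken over all windows. Groups used every window that holds a position, while profiles and these counts used the window centred on it.

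Named regions were the 3 with the highest mean rise and the 3 with the deepest mean fall in each comparison, after called windows up to 2 kb apart (or bins up to 1 bin apart) were joined and regions of fewer than 3 windows or 2 bins were left out. Their printed p is the highest adjusted p of their windows or bins. After the values were seen, the description was narrowed mainly to regions whose call held with each library left out in turn, and the others are given with the p without the library concerned. Positions were counted as near each other when under 1000 bp apart, since lists of single bases almost never overlap by the 1 bp that had been planned, and 100 random placements on the same chromosomes gave the share by chance. Data were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the R package data.table, version 1.17.8.

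The comparisons, tests and most alternatives were chosen before the data were examined. The alternatives were other filters, bin sizes and pseudocounts, each library centred on its median, the replicate number as a block, each library left out in turn, an estimated correlation, levels on autosomes or away from positions, and H3K9me2 relative to H3. Centring used the median over all windows kept before the filter, not that of the windows tested. Division by the library mean, identical positions, set tests with a library left out, other levels for high H3K27me3 and windows as listed were added after the data were seen. The fit was tested on simulated data in which all libraries of a mark had the same means and independent noise with the fitted spread. In these, 200 windows or bins were changed in the EpiLC libraries. The noise held no deviation shared across a library, so the false calls below need not hold for the real data. A log2 change of 1 was called in 44%, 92% and 100% of the changed ones for H3K27me3, H3K9me2 and H3, a change of 2 in 100%, 98% and 98%, and 20, 27 and 56 unchanged ones were called.

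Gene-level tests and gene lists had been planned but were not run, because the gene table at hand is on another build than mm9 and coordinates were not converted. Naming peaks by their score and splitting lists by score were not possible without scores. Tests on counts were not run because the files hold no counts. H3K4me3 and H3K27ac were not compared between cell types, since their lists combine them, and input libraries were not used here.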

Results

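Mouse embryonic stem cells (ESCs) were led toward a germ cell fate in culture, and their chromatin was profiled on the way by chromatin immunoprecipitation and sequencing (ChIP-seq). ESCs were induced into epiblast-like cells (EpiLCs), which resemble the epiblast of the early embryo, for 48 h. EpiLCs were then grown as floating aggregates, either for 2 days with the cytokine LIF alone at 1000 U/mL (d2LIF_Ag) or with LIF and the signalling protein BMP4 at 500 ng/mL, which gives primordial germ cell-like cells (PGCLCs). PGCLCs were taken on day 2 (d2PGCLC) and on day 6 (d6PGCLC), where the medium is listed with BMP8a at 500 ng/mL, SCF at 100 ng/mL and EGF at 50 ng/mL as further additions. The PGCLCs of this line were sorted for a Blimp1-mVenus reporter. A second line, induced into EpiLCs for 36 h, carried EGFP-tagged BLIMP1, a transcriptional repressor needed for germ cell specification, and was sorted by surface proteins. The series set out to measure how the amounts and places of histone marks change over these steps.

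The values used here came from 26 libraries with a signal for every 2-kb window, with 2 libraries per group. They covered H3K27me3, the mark left by Polycomb repressive complexes, in 5 cell types, and H3K9me2, a repressive mark of broad domains, and total histone H3 in 4 cell types, without d2LIF_Ag. A further 4 lists gave positions of H3K4me3 (a mark of promoters), of H3K27ac (a mark of active promoters and enhancers), and of EGFP-BLIMP1 in d2PGCLC and in d6PGCLC. Read depth is unknown, since no file holds counts. Values below are means ± SD of the 2 libraries of a group (n = 2). The labels number the replicates but do not say that they were separate cultures, so p-values measure only the spread between these samples, which may be technical. With 2 libraries against 2, an exact permutation test of a library level cannot give a two-sided p below 0.33, so levels are given without p-values.

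The mean H3K27me3 signal over all windows was 0.911 and 0.900 in the ESC libraries and 0.321 and 0.316 in the EpiLC libraries, a ratio of 0.352. On day 2 it was lower again, at 0.137 in both d2LIF_Ag libraries and 0.127 in both d2PGCLC libraries, or 0.430 and 0.398 times the EpiLC mean. In d6PGCLC it stood at 0.424 and 0.437, which was 3.39 times the d2PGCLC mean and 0.475 times the ESC mean. H3K9me2 followed another course, with means of 1.04 and 1.03 in ESCs, 0.691 and 0.680 in EpiLCs and 0.685 and 0.679 in d2PGCLC, and then 0.206 and 0.220 in d6PGCLC, which was 0.312 times the d2PGCLC mean. Total H3 had a mean between 0.999 and 1.01 in all 8 of its libraries. Replicate means differed far less than those of the cell types, but the authors' formula is not stated, and a scaling per cell type would by itself make the 2 means nearly equal. For this reason counts of changed windows are given below as deposited and again after each library was centred on its median or divided by its mean, which asks where in the genome signal was redistributed. In each region named below both libraries of one group lay above both of the other.

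**Figure D1:**
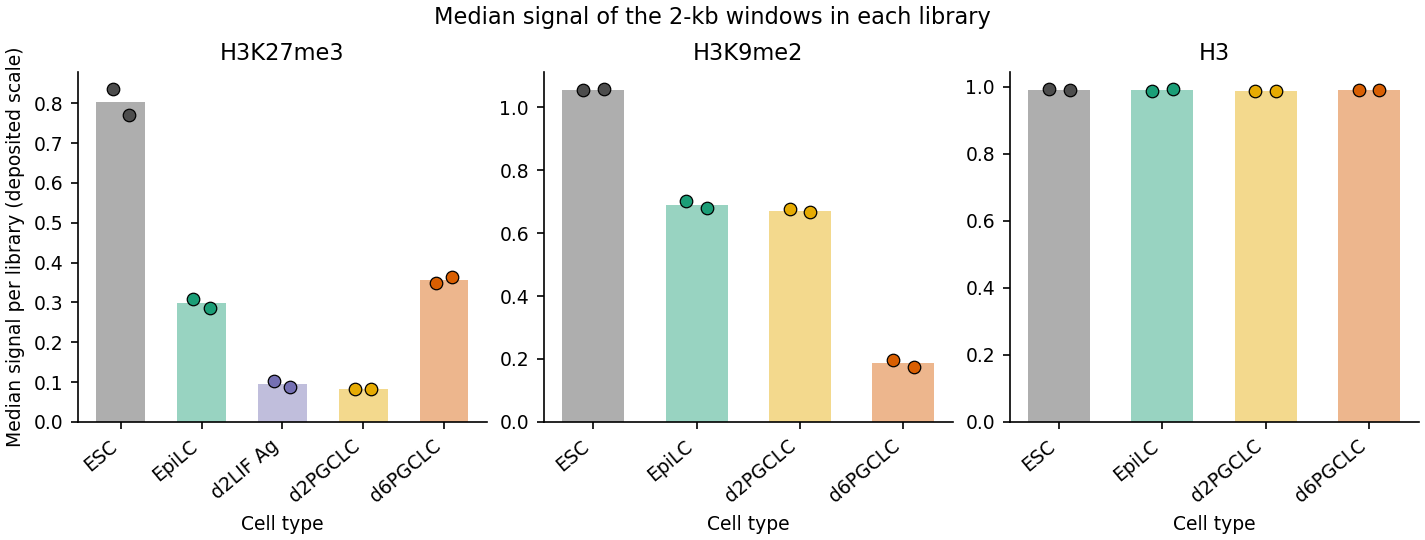
Median signal per 2-kb window (vertical axis, signal as deposited) in each library of H3K27me3, H3K9me2 and H3, with bars for the mean of the 2 libraries of a cell type and points for the libraries. The median of H3K27me3 was 0.803 in ESC, 0.298 in EpiLC, 0.0949 in d2LIF_Ag, 0.0829 in d2PGCLC and 0.356 in d6PGCLC.

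The first comparison asked what happened to H3K27me3 when ESCs became EpiLCs. Signal fell nearly everywhere, and in the regions with the deepest losses it went from above the ESC mean to below the EpiLC mean of 0.318. The region on chromosome 9 from 71612001 to 71622001 (build mm9), which holds 1 H3K4me3 position and 3 H3K27ac positions, had a signal of 3.97 ± 0.644 in ESC and 0.170 ± 0.0359 in EpiLC, a log2 change of -4.32, or -2.73 relative to the median change (adjusted p = 1.14e-07). Neighbouring regions of chromosome 10 did likewise, from 2.54 ± 0.00332 to 0.115 ± 0.0577 between 77530001 and 77536001 and from 2.57 ± 0.0671 to 0.191 ± 0.0463 between 77494001 and 77510001. A few places gained the mark against this trend. On chromosome 11 from 68194001 to 68216001, with 5 H3K4me3 positions, signal rose from 0.242 ± 0.0260 to 1.36 ± 0.00141 (adjusted p = 0.0156, or 0.0609 without ESC replicate 1 and 0.0788 without EpiLC replicate 1). On chromosome 15 from 102752001 to 102772001 it rose from 0.341 ± 0.0643 to 1.52 ± 0.184 (adjusted p = 0.00974, or 0.121 without ESC replicate 2 and 0.0811 without EpiLC replicate 1), and in d2LIF_Ag it stood at 4.97.

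Of 125772 windows tested with limma, 124067 were lower in EpiLC and 275 higher, with a median log2 change of -1.59. Relative to the loss over all windows, 5163 windows were lower and 1095 higher when libraries were centred, and 1848 and 1270 when they were divided by their means. The centred majority was not stable and turned to higher windows without EpiLC replicate 1. The centred total of 6258 was 2805 without ESC replicate 1, 1259 without ESC replicate 2 and 993 without EpiLC replicate 1. Windows at H3K4me3 positions lost less than other windows on the log2 scale, with a median 0.41 above that of all windows (camera, adjusted p = 5.11e-15, and adjusted p = 0.329 with an estimated correlation), a difference of 0.08 (adjusted p = 0.287) after division by the library mean. In the 10% of windows with the highest H3K27me3 their median lay on the other side, at -0.05 (adjusted p = 0.00288, with the test itself pointing up). Their mean signal was 0.649 ± 0.0440 times the library mean in ESC and 0.637 ± 0.00292 times in EpiLC.

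The next comparisons asked what 2 further days in aggregates did, without and with BMP4. In both d2LIF_Ag and d2PGCLC most of the genome lost more H3K27me3 while a minority of regions gained several-fold. The region on chromosome 17 from 36298001 to 36304001, with 3 H3K4me3 positions, rose from 0.278 ± 0.0918 in EpiLC to 2.16 ± 0.652 in d2LIF_Ag (log2 change 2.84, adjusted p = 7.68e-05) and 2.09 ± 0.204 in d2PGCLC (2.83, adjusted p = 0.00023). On chromosome 1 from 63310001 to 63318001 signal rose from 0.129 ± 0.00895 to 1.05 ± 0.265 and to 0.781 ± 0.00243. On chromosome X from 7494001 to 7508001, with 3 H3K4me3 positions and 1 EGFP-BLIMP1 position of day 2, it rose from 0.290 ± 0.0264 in EpiLC to 1.78 ± 0.125 in d2PGCLC (adjusted p = 1.01e-05). In the other direction, chromosome 2 from 116374001 to 116388001 fell from 2.12 ± 0.278 to 0.214 ± 0.189 in d2LIF_Ag and 0.112 ± 0.0305 in d2PGCLC, and chromosome 2 from 165206001 to 165212001 fell from 1.48 ± 0.241 to 0.174 ± 0.140 and 0.0985 ± 0.0379. Neither of these falling regions holds a listed H3K4me3, H3K27ac or EGFP-BLIMP1 position.

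As deposited, 90514 windows were lower and 7577 higher in d2LIF_Ag than in EpiLC, with a median log2 change of -0.91, and 84970 were lower and 5328 higher in d2PGCLC (3395 higher without EpiLC replicate 1 and 2935 without d2PGCLC replicate 2), with a median of -0.83. These directions turned when each library was set against its median or mean over all windows. After centring, 41556 windows were higher and 1324 lower in d2LIF_Ag, a total of 42880 that was 22552 without EpiLC replicate 1 and 22016 without d2LIF_Ag replicate 2, and 62540 were higher and 2246 lower in d2PGCLC, a total of 64786 that was 36873 without EpiLC replicate 1. After division by the mean, 33216 windows were higher and 4535 lower in d2LIF_Ag, and 48613 and 5667 in d2PGCLC. The windows tested were the 10% with the highest mean signal. Over all windows the log2 ratio of group medians, taken without the pseudocount, was -1.65 in d2LIF_Ag and -1.84 in d2PGCLC. The pseudocount draws changes toward 0, so these ratios overstate how much less the tested windows fell than the median that set the centre. A majority of higher calls after centring may largely follow from this filter and centre, and does not describe the whole genome.

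H3K4me3 positions stood out on day 2 relative to the library mean, which had fallen. As deposited, the mean H3K27me3 in their windows was 0.620 ± 0.0369 in ESC and 0.214 ± 0.00328 in EpiLC. It was 0.253 ± 0.0241 in d2LIF_Ag, 0.196 ± 0.0221 in d2PGCLC and 0.376 ± 0.0705 in d6PGCLC. The deposited level in d2PGCLC was thus no higher than in EpiLC, and that in d2LIF_Ag only slightly higher. Relative to the library mean, H3K27me3 in their windows was 0.649 ± 0.0440 in ESC and 0.637 ± 0.00292 in EpiLC, and it was 1.75 ± 0.173 in d2LIF_Ag and 1.47 ± 0.169 in d2PGCLC, then 0.831 ± 0.173 in d6PGCLC. A minority of windows raised these means. Set against the library median rather than its mean, the median window stood at 0.256 ± 0.00831 in ESC and 0.329 ± 0.0713 in EpiLC. It stood at 0.607 ± 0.0423 in d2LIF_Ag, 0.483 ± 0.105 in d2PGCLC and 0.447 ± 0.212 in d6PGCLC. The 2 scales have different denominators, so their values cannot be compared directly. On the log2 scale their median change from EpiLC lay 0.86 above that of all windows in d2LIF_Ag (camera, adjusted p = 1.57e-63) and 0.71 above it in d2PGCLC (adjusted p = 4.31e-44), both with adjusted p = 0.322 with an estimated correlation. H3K27ac positions near an H3K4me3 position moved the same way, by 0.87 in d2LIF_Ag (adjusted p = 1.32e-52) and 0.67 in d2PGCLC (adjusted p = 2.43e-31), again with adjusted p = 0.322 with an estimated correlation. After division by the library mean the differences were smaller, with 0.57 and 0.37 at H3K4me3 positions and 0.53 and 0.26 at H3K27ac positions near them. In the 10% of windows with the highest H3K27me3 they were 1.55 (adjusted p = 8.24e-102) and 1.22 (adjusted p = 1.52e-75) at H3K4me3 positions, and 1.21 (adjusted p = 1.35e-44) and 0.66 (adjusted p = 3.01e-18) at H3K27ac positions near them. That filter counts the day 2 libraries, so windows low in ESC and EpiLC may pass it through their day 2 signal. The larger differences may partly follow from this. H3K27ac positions away from H3K4me3 changed less, with 0.39 in d2LIF_Ag (adjusted p = 1.85e-11, and 0.395 with an estimated correlation), or 0.12 in those top windows (adjusted p = 0.0141). In d2PGCLC the difference at the latter was 0.21 (adjusted p = 9.58e-05, and adjusted p = 0.536 with an estimated correlation), and it missed the threshold after centring (adjusted p = 0.240) and in the 10% of windows with the highest H3K27me3, where it was -0.24 (adjusted p = 0.129).

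**Figure D2:**
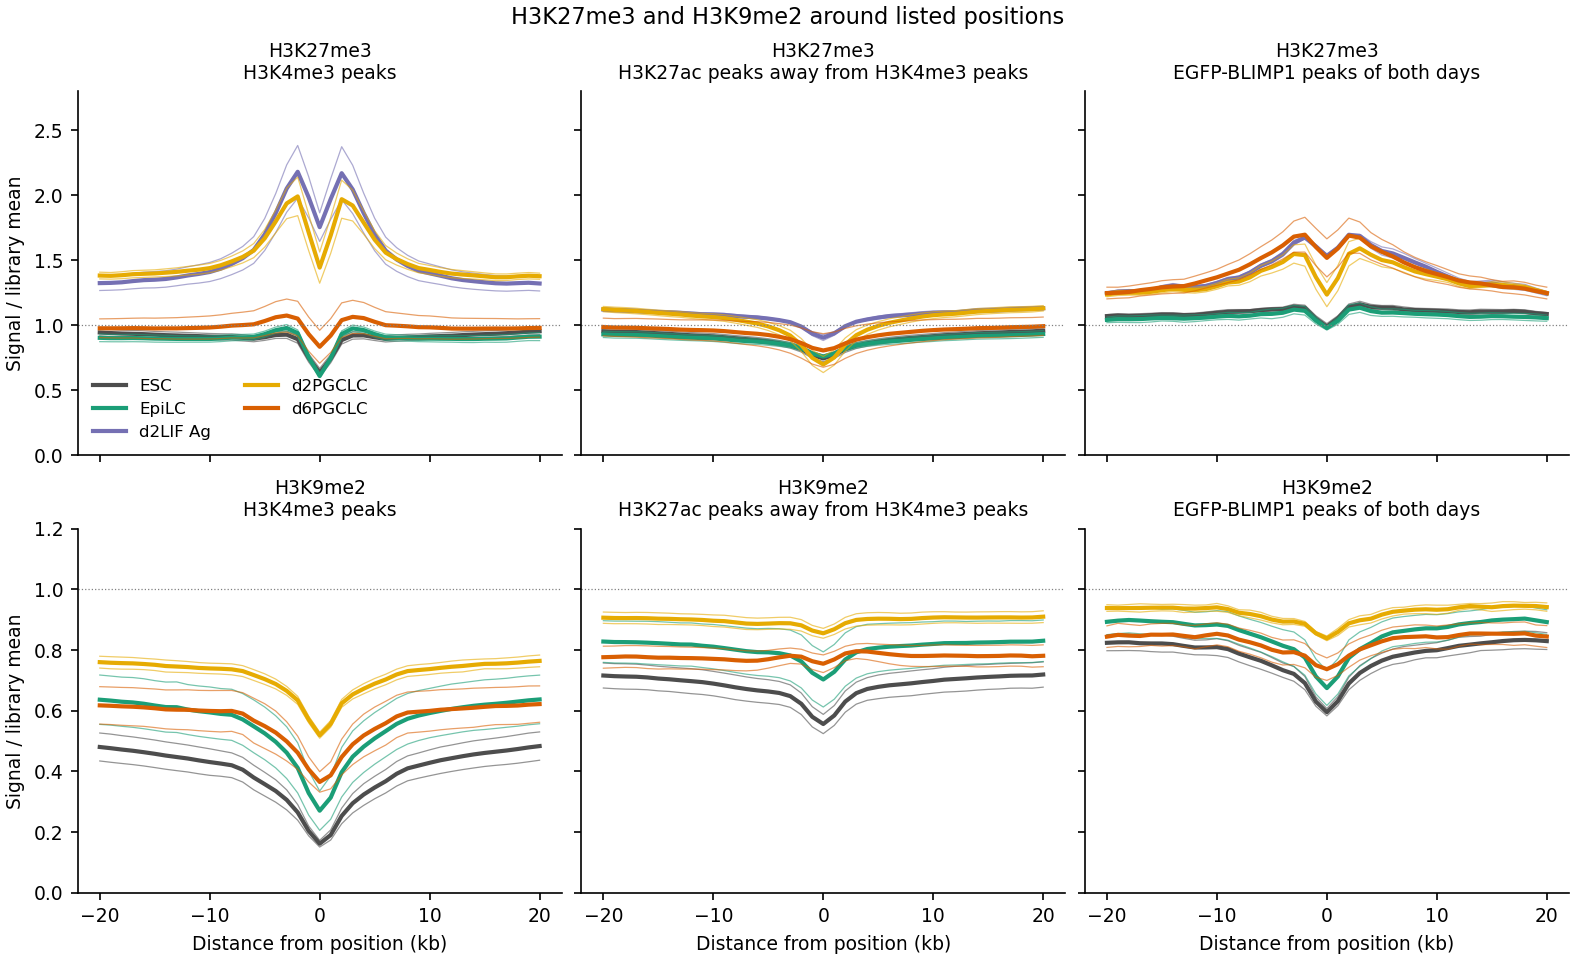
Signal divided by the library mean (vertical axis) against distance in kb from H3K4me3 positions, H3K27ac positions away from H3K4me3, and EGFP-BLIMP1 positions of both days, for H3K27me3 and H3K9me2, with thin lines for libraries, thick lines for the mean of 2 and a dotted line at 1. In the window centred on H3K4me3 positions, H3K27me3 was 0.610 times the library mean over all windows in EpiLC, 1.75 times in d2LIF_Ag and 1.44 times in d2PGCLC.

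Counted position by position, 5320 of 38406 H3K4me3 positions (13.9%) lay in windows with H3K27me3 of at least 3 times the library mean in both libraries of d2LIF_Ag, and 5040 (13.1%) in d2PGCLC. ESC had 753 such positions (1.96%), EpiLC 464 (1.21%) and d6PGCLC 1829 (4.76%). In single libraries, replicate 1 and then 2, the counts were 5685 and 6454 in d2LIF_Ag, 5290 and 5668 in d2PGCLC, 830 and 1435 in ESC, 565 and 918 in EpiLC, and 2843 and 2199 in d6PGCLC. Windows without any listed position reached that level in 2.39% of cases in ESC, 1.4% in EpiLC, 2.99% in d2LIF_Ag, 4.44% in d2PGCLC and 2.63% in d6PGCLC. Of the d2PGCLC positions, 4265 (84.6%) also passed in d2LIF_Ag, where independent lists would share 698, and of the d6PGCLC positions 1488 (81.4%) also passed in d2PGCLC, where independent lists would share 240.02. A group of 3729 positions passed in both day 2 types and not in ESC, while 165 passed in ESC and not in d2PGCLC. The cut-off follows the library mean, which was 0.905 in ESC, 0.137 in d2LIF_Ag and 0.127 in d2PGCLC. A position can therefore pass on day 2 and not in ESC although its deposited signal fell, so these counts do not show a gain of the mark. The level of 3 was chosen after the data were seen. At 5 times the mean the shares were 0.0989% in ESC, 0.133% in EpiLC, 8.87% in d2LIF_Ag, 7.80% in d2PGCLC and 0.932% in d6PGCLC, where the single libraries had 967 and 413 positions and both together 358, while ESC had 44 and 117 against 38 and EpiLC 71 and 112 against 51. The H3K4me3 list combines all cell types, so it does not say in which of them a position carried H3K4me3.

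**Figure D3:**
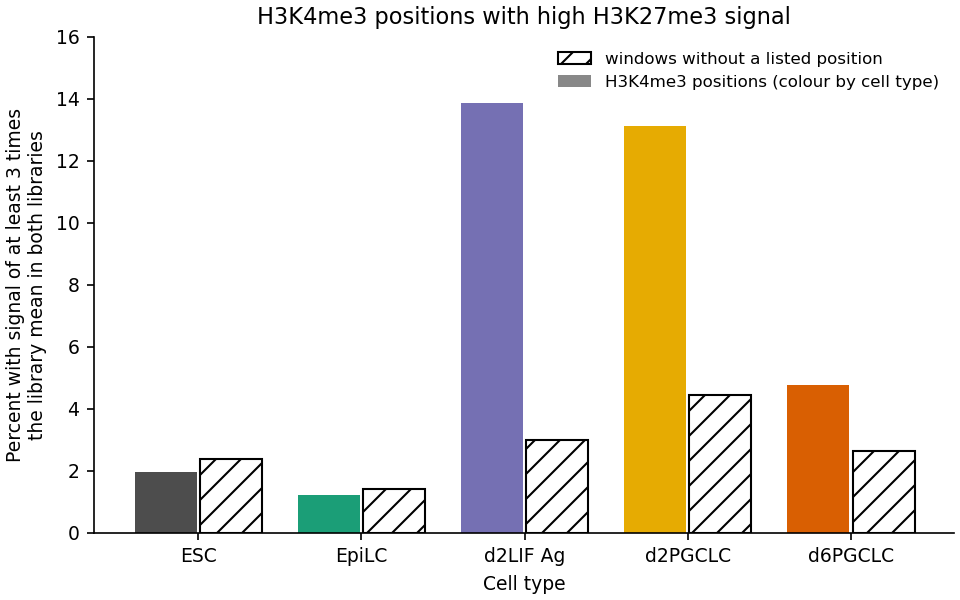
Percent (vertical axis) of 38406 H3K4me3 positions, and of windows without listed positions, with H3K27me3 of at least 3 times the library mean in both libraries of each cell type. Among H3K4me3 positions the share was 13.9% in d2LIF_Ag and 13.1% in d2PGCLC, against 1.96% in ESC and 1.21% in EpiLC.

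The comparison of d2PGCLC with d2LIF_Ag set cells grown with BMP4 and sorted for the reporter against aggregates grown without BMP4, and the culture and the sort cannot be told apart in it. As deposited it gave fewer called windows than the other comparisons of H3K27me3, while after division by the library mean it gave 5399 against 3118 for EpiLC and ESC. On chromosome 14 from 98416001 to 98426001, which holds 1 EGFP-BLIMP1 position of each day and 1 H3K27ac position, H3K27me3 was 0.163 ± 0.0388 in d2LIF_Ag and 0.877 ± 0.0141 in d2PGCLC (log2 change 2.16, adjusted p = 0.00017), with 1.61 in ESC. On chromosome 11 from 87980001 to 87986001 it was 0.184 ± 0.00658 and 0.732 ± 0.0608 (adjusted p = 0.00128). The region on chromosome 13 from 53548001 to 53584001, with 4 H3K4me3 and 10 H3K27ac positions, had 1.89 ± 0.331 in d2LIF_Ag and 0.258 ± 0.102 in d2PGCLC (log2 change -2.79, adjusted p = 0.0124), a call that was lost without d2LIF_Ag replicate 2 (adjusted p = 0.0936), without d2PGCLC replicate 1 (0.327) and after centring (0.068).

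In all, 3307 windows were lower and 773 higher in d2PGCLC, with a median log2 change of 0.05. After centring 2107 were lower and 1438 higher, and after division by the mean 2952 and 2447. The centred majority was not stable and turned to higher windows in at least 1 fit with a library left out. The total of 4080 was 818 without d2PGCLC replicate 1, 2541 without d2LIF_Ag replicate 2 and 2675 without d2PGCLC replicate 2, and the centred total of 3545 was 1013 without d2PGCLC replicate 1. By groups of positions, H3K27me3 was lower in d2PGCLC at H3K27ac positions near H3K4me3 (-0.18 against all windows, camera, adjusted p = 6.52e-06, and adjusted p = 0.536 with an estimated correlation), at H3K27ac positions away from it (-0.16, adjusted p = 2.05e-07, and 0.468 with an estimated correlation) and at EGFP-BLIMP1 positions of day 2 (-0.14, adjusted p = 4.31e-06, and 0.409 with an estimated correlation). At H3K4me3 positions the difference was -0.14 (adjusted p = 0.000525, and 0.545 with an estimated correlation), but adjusted p was 0.249 without d2PGCLC replicate 1 and 0.0708 without d2LIF_Ag replicate 2. In the 10% of windows with the highest H3K27me3 these 4 differences were -0.49, -0.31, -0.27 and -0.34, and after division by the mean -0.26, -0.21, -0.17 and -0.19.

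From d2PGCLC to d6PGCLC, H3K27me3 came back over most of the genome. In the regions with the strongest gains, signal on day 2 was somewhat above the library mean of 0.127. On chromosome 9 from 122180001 to 122186001 signal rose from 0.197 ± 0.0364 to 3.59 ± 0.110 (log2 change 3.93, or 2.62 relative to the median change, adjusted p = 6.85e-07), above the ESC value of 2.50. On chromosome 13 from 70514001 to 70526001, where EGFP-BLIMP1 is listed on both days, it rose from 0.156 ± 0.00928 to 2.94 ± 0.254 (adjusted p = 2.25e-09), and on chromosome 11 from 58016001 to 58022001 from 0.179 ± 0.0996 to 2.93 ± 0.232 (adjusted p = 1.52e-05). A small set of regions ran the other way, such as chromosome 10 from 79382001 to 79388001, with 2 H3K4me3 positions, where signal fell from 1.60 ± 0.147 to a mean of 0.478 (adjusted p = 0.00364, or 0.101 without d6PGCLC replicate 2).

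As deposited, 106017 windows were higher and 1450 lower in d6PGCLC, with a median log2 change of 1.31. The lower windows numbered 724 without d2PGCLC replicate 2, 2628 without d6PGCLC replicate 1 and 963 without d6PGCLC replicate 2. Relative to the gain over all windows the balance turned, with 43717 windows lower and 8791 higher after centring (fewer higher without d2PGCLC replicate 1 or d2PGCLC replicate 2) and 46659 and 10894 after division by the mean. Over all windows the log2 ratio of group medians was 2.10, more than the median change of the tested windows. This ratio holds no pseudocount, so it overstates the gap. The turn after centring may largely follow from the filter and the centre. H3K4me3 positions gained less than other windows, by -0.55 (camera, adjusted p = 1.46e-26), and so did H3K27ac positions near them, by -0.51 (adjusted p = 9.11e-25), each with adjusted p = 0.322 with an estimated correlation. After division by the mean these differences were -0.21 (adjusted p = 1.48e-07) and -0.08 (adjusted p = 0.0425), and in the 10% of windows with the highest H3K27me3 -0.82 (adjusted p = 8.46e-35) and -0.56 (adjusted p = 9.84e-22). Chromosome X gained less as well, by -0.27 (adjusted p = 3.68e-10, and 0.322 with an estimated correlation), or by -0.18 after division by the mean (adjusted p = 0.0245) and -0.28 in those top windows (adjusted p = 0.000967). Relative to the library mean X stood at 0.769 and 0.749 in the d2PGCLC libraries and at 0.649 and 0.751 in those of d6PGCLC. No other chromosome was tested as a group. On this measure chromosome 11 fell from 1.35 to 1.22, while chromosome 5 rose from 1.05 to 1.19. EGFP-BLIMP1 positions of both days had a median 0.24 above all windows, which missed the threshold as deposited (adjusted p = 0.122, and 0.706 with an estimated correlation). With 1 library left out the adjusted p ran from 0.00282 without d6PGCLC replicate 2 to 0.656 without d6PGCLC replicate 1, and was 0.0241 without d2PGCLC replicate 2. In the 10% of windows with the highest H3K27me3 it was 0.334, and it passed the threshold after centring (adjusted p = 8.96e-06) and after division by the mean (adjusted p = 0.000358). Their H3K27me3 relative to the library mean was 0.955 ± 0.0312 in ESC, 0.943 ± 0.0249 in EpiLC, 1.48 ± 0.0205 in d2LIF_Ag, 1.21 ± 0.128 in d2PGCLC and 1.46 ± 0.196 in d6PGCLC.

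Set against the ESCs from which they were derived, d6PGCLC carried less H3K27me3 at most places and more at some. The region on chromosome 17 from 36298001 to 36304001 had 0.179 ± 0.0434 in ESC and 2.28 ± 1.09 in d6PGCLC (log2 change 3.40, adjusted p = 1.47e-05), and chromosome 7 from 146760001 to 146776001, with 3 H3K4me3 positions, had 0.311 ± 0.0281 and 2.52 ± 0.632 (adjusted p = 5.24e-05). Losses were of similar depth on chromosome X from 35168001 to 35178001 (3.88 ± 0.330 to 0.262 ± 0.152, adjusted p = 1.26e-05), chromosome 3 from 9238001 to 9250001 (2.90 ± 0.220 to 0.198 ± 0.0510) and chromosome 8 from 35792001 to 35806001 (3.37 ± 0.234 to 0.261 ± 0.133). As deposited 104594 windows were lower and 1676 higher, with a median of -1.08. After centring 14161 were lower and 13895 higher, and after division by the mean the numbers were 16720 and 14233. The centred total of 28056 was much lower without ESC replicate 1 or ESC replicate 2. The balance of the 2 directions also moved with single libraries. EGFP-BLIMP1 positions of both days kept more of the mark than other windows, by 0.58 (camera, adjusted p = 1.57e-16), as did H3K4me3 positions, by 0.68 (adjusted p = 1.28e-17), each with adjusted p = 0.322 with an estimated correlation. After division by the mean the differences were 0.45 and 0.34, and in the 10% of windows with the highest H3K27me3 they were 0.57 and 0.33.

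**Figure D4:**
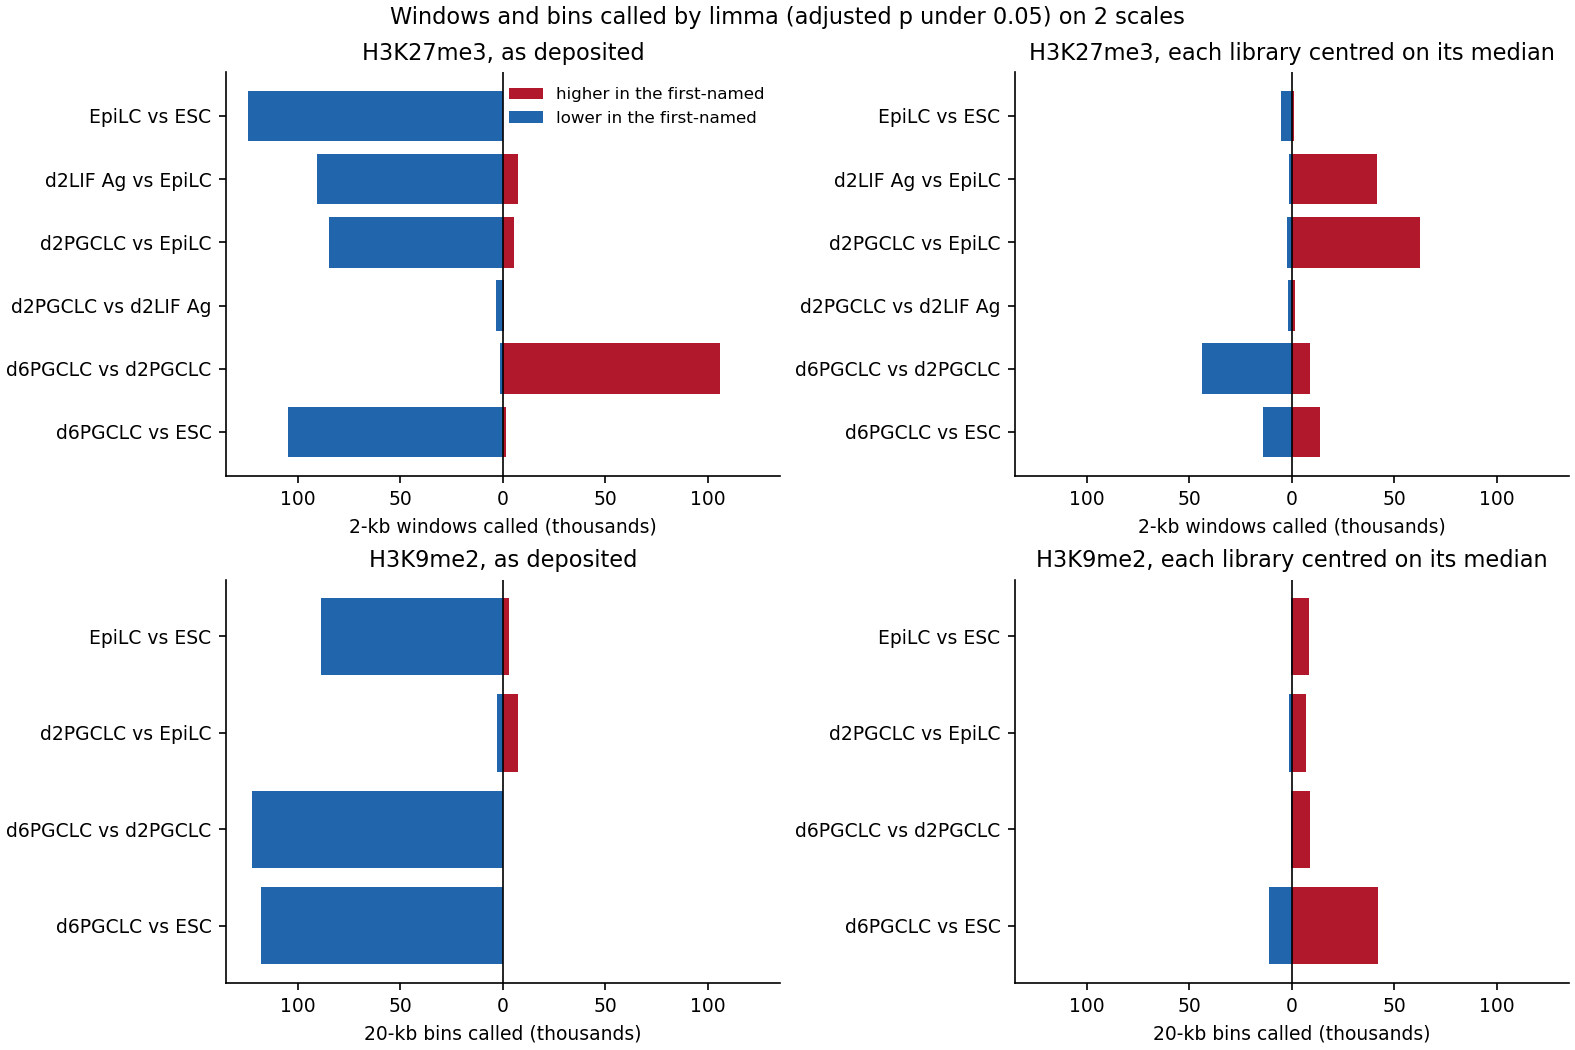
Windows of H3K27me3 and 20-kb bins of H3K9me2 called by limma (horizontal axis, in units of 1000) in each comparison, as deposited and after centring each library on its median over all windows, with red for higher and blue for lower in the cell type named first. From EpiLC to d2PGCLC, 84970 windows were lower and 5328 higher as deposited, and 2246 lower and 62540 higher after centring.

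H3K9me2 was compared in 20-kb bins, whose coordinates are given as the files list them, 2 kb downstream of the position lists. From ESC to EpiLC it declined over most of the genome and rose in some places where ESCs had carried little. On chromosome 1 from 120520001 to 120580001 signal rose from 0.179 ± 0.0932 to 0.749 ± 0.0983 (log2 change 1.58, adjusted p = 0.000814), and it was 0.672 in d2PGCLC and 0.127 in d6PGCLC. On chromosome 17 from 37100001 to 37160001 it rose from 0.104 ± 0.0226 to 0.447 ± 0.197 (adjusted p = 0.00132, or 0.0933 after division by the library mean). At H3K4me3 positions H3K9me2 was 0.179 ± 0.0181 times the library mean in ESC and 0.294 ± 0.0965 times in EpiLC, and their median change lay 0.65 above that of all windows (camera, adjusted p = 1.29e-49, and 0.189 with an estimated correlation), or 0.23 after division by the mean. H3K27ac positions away from H3K4me3 stood 0.40 above all windows (adjusted p = 2.37e-20, and 0.201 with an estimated correlation). In the 10% of windows with the highest H3K9me2 these differences were -0.09 at H3K4me3 positions (adjusted p = 0.00767, with the test itself pointing up) and 0.06 at H3K27ac positions away from them (adjusted p = 0.098). Of 126816 bins, 88745 were lower and 3215 higher in EpiLC, with a median log2 change of -0.52. The higher bins numbered 1070 without ESC replicate 1, 5175 without ESC replicate 2, 6974 without EpiLC replicate 1 and 782 without EpiLC replicate 2. After centring 8421 were higher and 252 lower, a total of 8673 that was 3 without ESC replicate 1, 15480 without EpiLC replicate 1 and 2164 without EpiLC replicate 2, and after division by the mean 49 were higher and 11 lower.

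Between EpiLC and d2PGCLC the mean deposited signal of H3K9me2 hardly differed, while H3K4me3 positions and the H3K27ac positions near them, which were low in EpiLC, rose. The signal was also flatter, with a 90th percentile of 1.18 ± 0.0474 in EpiLC and 1.05 ± 0.00212 in d2PGCLC. Whether the rises at positions go beyond this was not tested. The share of the library mean found at H3K4me3 positions went from 0.294 ± 0.0965 to 0.540 ± 0.0147, and that at H3K27ac positions near them from 0.247 ± 0.0924 to 0.503 ± 0.0160. These windows rose against all others by 0.76 (camera, adjusted p = 1.72e-41, and 0.194 with an estimated correlation) and 0.83 (adjusted p = 5.51e-48, and 0.189 with an estimated correlation), or by 0.58 and 0.62 after division by the mean. At EGFP-BLIMP1 positions of both days the difference was 0.37 (adjusted p = 9.3e-11, and 0.201 with an estimated correlation). At H3K27ac positions away from H3K4me3, which stood at 0.710 ± 0.126 times the library mean in EpiLC and 0.854 ± 0.0228 times in d2PGCLC, it was 0.31 (adjusted p = 1.91e-08, and 0.336 with an estimated correlation). In the 10% of windows with the highest H3K9me2 the differences were 0.32 at H3K4me3 positions (adjusted p = 4.69e-12), 0.15 at H3K27ac positions near them (adjusted p = 0.0887), 0.03 at EGFP-BLIMP1 positions of both days (adjusted p = 0.659) and 0.01 at H3K27ac positions away from H3K4me3 (adjusted p = 0.688), so the last 3 calls were lost there. In single bins the result was not stable. As deposited there were 7618 higher and 2773 lower bins, a total of 10391 that was 3 without d2PGCLC replicate 1, 2 without d2PGCLC replicate 2, 1509 without EpiLC replicate 1 and 17580 without EpiLC replicate 2. After centring 6743 were higher and 1383 lower, a total of 8126 that was 1785 without EpiLC replicate 1 and 16116 without EpiLC replicate 2, while limma called 0 bins without d2PGCLC replicate 1 (16148 at an unadjusted p under 0.05) or d2PGCLC replicate 2 (18795). Division by the mean gave 3548 higher and 1055 lower bins. The largest rise, on chromosome X from 47900001 to 48000001, went from 0.0506 ± 0.0207 to 0.347 ± 0.00546 (adjusted p = 0.0115) and was lost without d2PGCLC replicate 1 (0.210) or replicate 2 (0.131).

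At the step to d6PGCLC the deposited level of H3K9me2 dropped over most of the genome. As deposited nearly all bins fell, so called bins joined into long stretches. On chromosome 16 from 94340001 to 98260001 signal fell from 0.953 ± 0.0455 to 0.204 ± 0.0208 (log2 change -1.71, adjusted p = 0.0199), which is -0.39 relative to the median change, while H3 was 1.44 and 1.45. This call was lost without d2PGCLC replicate 1 (adjusted p = 0.0655), d2PGCLC replicate 2 (0.0617) or d6PGCLC replicate 1 (0.324), and after centring (0.978). In all 122234 bins were lower and 62 higher (355 without d6PGCLC replicate 1 and 41 without d6PGCLC replicate 2), with a median of -1.33. After centring 8785 were higher and 673 lower, but that total of 9458 was 3 without d2PGCLC replicate 1, 21401 without d6PGCLC replicate 1 and 539 without d6PGCLC replicate 2. Without d2PGCLC replicate 2 limma called 0 bins, with 18205 at an unadjusted p under 0.05. Division by the mean gave 10357 higher and 9190 lower bins. Chromosome X kept more of the mark than other windows, by 0.14 (camera, adjusted p = 4.17e-08, and 0.0986 with an estimated correlation), or 0.15 after division by the mean and 0.20 in the 10% of windows with the highest H3K9me2, with 1.05 ± 0.0339 times the library mean in d2PGCLC and 1.24 ± 0.127 times in d6PGCLC. X was the only chromosome tested as a group, and the rise was not particular to it. Relative to the library mean, chromosome 15 went from 0.956 to 1.13 and chromosome 19 from 0.887 to 1.05. Others fell, such as chromosome 16 from 1.35 to 1.15. At H3K4me3 positions the difference was 0.08 as deposited (adjusted p = 0.0268, and 0.781 with an estimated correlation) and turned to -0.26 after division by the mean (adjusted p = 3.63e-12), while in the 10% of windows with the highest H3K9me2 it was 0.37 (adjusted p = 9.33e-18). H3K27ac positions near them likewise had 0.10 as deposited (adjusted p = 0.0378, and 0.782 with an estimated correlation), -0.26 after division (adjusted p = 1.41e-13) and 0.66 in the top windows (adjusted p = 2.16e-16), so the direction at both depended on the scaling and the windows used. After centring neither passed (adjusted p = 0.229 and 0.102). The call as deposited at H3K4me3 positions was lost without any of 7 of the 8 libraries, with adjusted p = 0.411 without ESC replicate 1, 0.439 without ESC replicate 2, 0.693 without EpiLC replicate 1, 0.745 without EpiLC replicate 2, 0.321 without d2PGCLC replicate 1, 0.0845 without d2PGCLC replicate 2 and 0.256 without d6PGCLC replicate 1 in this test of H3K9me2. The call at H3K27ac positions near them was lost without any of the same 7, with adjusted p of up to 0.996, without EpiLC replicate 2.

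Compared with ESCs, d6PGCLC had 118041 bins lower in H3K9me2 and 53 higher (30 without ESC replicate 1 or ESC replicate 2), with a median log2 change of -1.74. One of the deepest losses that held with any library left out was on chromosome 12 from 84420001 to 84460001, from 1.39 ± 0.106 to 0.177 ± 0.0259 (log2 change -2.34, adjusted p = 8.7e-10). At H3K4me3 positions, the signal relative to the library mean was 0.385 ± 0.0509 against 0.179 ± 0.0181 in ESC, but as deposited it fell from 0.187 ± 0.0169 in ESC to 0.0824 ± 0.00713. These windows lay 1.58 above all others in their change (camera, adjusted p = 2.8e-87, and 0.162 with an estimated correlation), and by 0.50 after division by the mean (adjusted p = 1.36e-24) and 0.57 in the 10% of windows with the highest H3K9me2 (adjusted p = 1.06e-38). Their deposited level in d6PGCLC was below the pseudocount of 0.123, which draws such changes toward 0. The difference of 1.58 may partly follow from this and does not show that these windows kept or gained the mark. The balance of bins depended on the scaling. After centring 42092 were higher and 10973 lower, a total of 53065 that was 31408 without d6PGCLC replicate 2, and after division by the mean 18687 were higher and 21844 lower.

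Total H3 served as the control for the amount of chromatin recovered at each place. Few of its 20-kb bins were called, though single chromosomes shifted, such as chromosome 8 from 1.05 ± 0.00261 times the library mean in ESC to 0.919 ± 0.00520 in d6PGCLC, and in 100-kb bins 4348 were called between these cell types. Of 126765 bins, 156 were higher and 38 lower from ESC to EpiLC, 13 and 65 from EpiLC to d2PGCLC, 25 and 3 from d2PGCLC to d6PGCLC, and 1226 and 1477 from ESC to d6PGCLC. On chromosome 15 from 3120001 to 3220001 H3 was 0.698 ± 0.0329 in ESC and 1.18 ± 0.0183 in EpiLC (log2 change 0.46, adjusted p = 0.0277), a call lost without ESC replicate 1 (0.0742), ESC replicate 2 (0.345), EpiLC replicate 1 (0.260) or EpiLC replicate 2 (0.153). The total of 194 for ESC to EpiLC was 104 without ESC replicate 1, 30 without ESC replicate 2, 52 without EpiLC replicate 1 and 64 without EpiLC replicate 2. That of 2703 for ESC to d6PGCLC was 446 without ESC replicate 1, 32 without ESC replicate 2, 160 without d6PGCLC replicate 1 and 842 without d6PGCLC replicate 2. The total of 78 for EpiLC to d2PGCLC was 35 without EpiLC replicate 1, 37 without d2PGCLC replicate 1 and 44 without d2PGCLC replicate 2, and that of 28 for d2PGCLC to d6PGCLC was 109 without d6PGCLC replicate 2.

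The lists of positions were used to ask where EGFP-BLIMP1 sits on each day. There were 7122 positions in d2PGCLC and 11224 in d6PGCLC. Of the d2PGCLC positions, 6098 (85.6%, Wilson 95% interval 84.8 to 86.4) had a d6PGCLC position under 1000 bp away, and of the d6PGCLC positions 54.4% (53.4 to 55.3) had a d2PGCLC position, where random placement on the same chromosomes gave 0.887% and 0.562%. At 6096 of them the listed base was identical in both lists. How the lists were made is not given in the sources used here. Separate calls would hardly give the identical base at nearly all shared positions, so the 2 lists probably draw on a common set of positions. The sharing, its contrast with random placement and the split into both days and 1 day then do not compare independent calls. H3K27ac lay under 1000 bp from 45.6% (44.4 to 46.7) of the d2PGCLC positions and from 40.2% (39.3 to 41.1) of the d6PGCLC positions (Fisher's exact test, two-sided p = 4.03e-13), against 5.95% and 6.05% at random. H3K4me3 lay near 17.5% (16.6 to 18.4) and 16.1% (15.5 to 16.8) (Fisher's exact test, two-sided p = 0.0183), against 2.84% and 2.88% at random. Since the lists share most positions of d2PGCLC, these 2 tests count shared positions on both sides and are not tests of independent lists.

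Positions present on both days differed from those of d6PGCLC alone. Near H3K27ac were 45.2% of the positions of both days, 48.1% of those of d2PGCLC alone and 34.2% of those of d6PGCLC alone (Fisher's exact test, two-sided, p = 1.83e-32 for both days against d6PGCLC alone, and 0.078 against d2PGCLC alone). Near H3K4me3 were 18.1%, 13.5% and 13.7% (p = 2.2e-10 and 0.000219 by the same exact test). Chromosome X held 354 of 6098 positions of both days (5.81%, 5.25 to 6.42), 29 of 1024 of d2PGCLC alone (2.83%, 1.98 to 4.04) and 52 of 5122 of d6PGCLC alone (1.02%, 0.775 to 1.33), while it held 6.28% of windows, 2.38% of H3K4me3 positions and 2.27% of H3K27ac positions. The share on X differed between both days and d6PGCLC alone (Fisher's exact test, two-sided p = 4.43e-47), and between both days and d2PGCLC alone (p = 3.51e-05 by the same exact test). These tests compare lists, not replicates, and the intervals cover counting error only. Of all 82730 H3K27ac positions, 23.3% lay near one of the 38406 H3K4me3 positions, and 48.5% of the latter lay near H3K27ac.

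**Figure D5:**
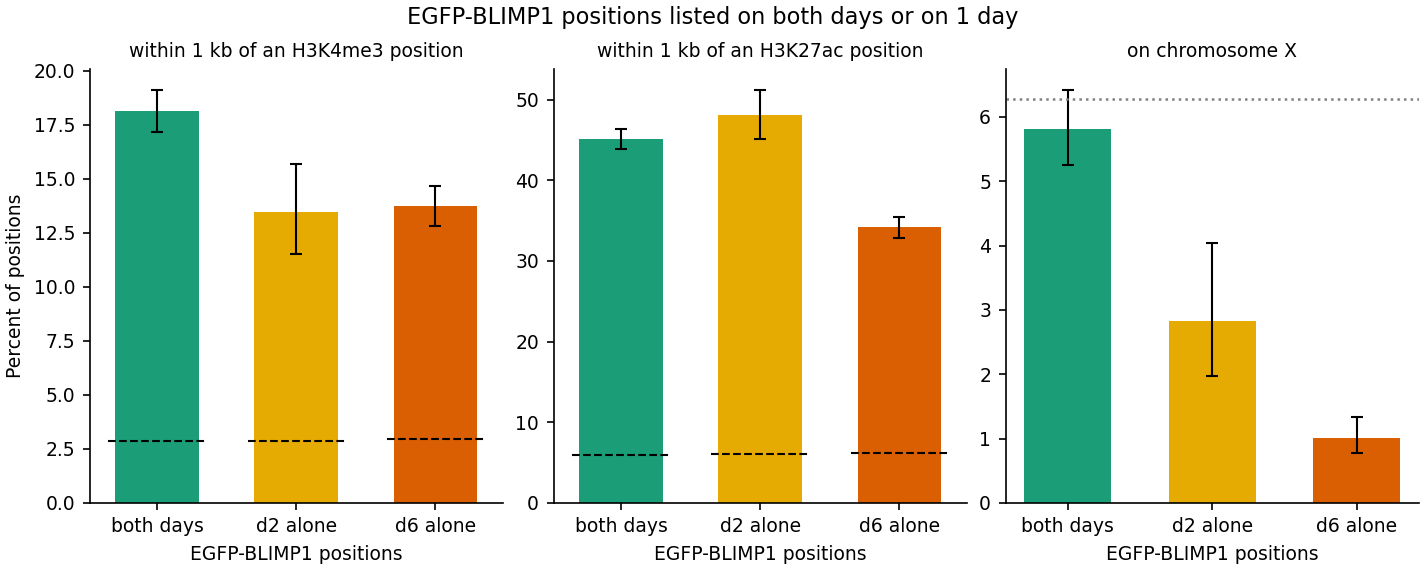
Percent (vertical axis) of EGFP-BLIMP1 positions of both days, d2PGCLC alone and d6PGCLC alone that lie near H3K4me3, near H3K27ac or on chromosome X, with Wilson 95% intervals as error bars, dashed lines for the mean of random placements and a dotted line for the share of windows on X. On X the shares were 5.81%, 2.83% and 1.02%.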

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

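The tests in this part were written before their values were computed, but the share of EGFP-BLIMP1 positions on chromosome X had been seen before its tests were chosen, and the values with 1 library left out and the check of H3 on X and Y, which set aside the planned reading of the H3 test, were added after the results were seen.

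The change of H3K27me3 from EpiLC differed between d2PGCLC and d2LIF_Ag in 4080 windows, tested as the difference of the 2 changes with limma, which is the same contrast as d2PGCLC against d2LIF_Ag. Of these, 3307 were lower and 773 higher in d2PGCLC. The number depended on single libraries and was 818 without d2PGCLC replicate 1, 2541 without d2LIF_Ag replicate 2 and 2675 without d2PGCLC replicate 2, so the windows may partly reflect differences between libraries.

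At EGFP-BLIMP1 positions of day 2, H3K27me3 was lower in d2PGCLC than in d2LIF_Ag, while a factor that recruits the mark could be expected to raise it there. Compared with other windows that hold an H3K4me3 or H3K27ac position and have a matched mean level, the 7086 windows with EGFP-BLIMP1 had a median change of -0.21 against -0.23 (each library divided by its mean), which was above 100% of 1000 matched sets. The difference of 0.0212 was small and rested on the choice of library, with a percentile of 91.7 without d2PGCLC replicate 1, 99.3 without d2PGCLC replicate 2, 100 without d2LIF_Ag replicate 1 and 0 without d2LIF_Ag replicate 2. A gain of H3K27me3 at bound sites and a spread between libraries cannot be told apart with 2 libraries per group. Binding was also mapped in the second line, with 36 h of EpiLC induction, and H3K27me3 in the first, with 48 h. The sites were thus not shown to be bound in the cells in which the mark was measured. Comparable sites without EGFP-BLIMP1 had a similarly lower signal, and its cause stays open.

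From d2PGCLC to d6PGCLC H3K27me3 rose while H3K9me2 fell, which raises the question whether 1 mark replaced the other at the same places. Across 100-kb bins, with each library divided by its mean, the 2 changes had a Spearman correlation of 0.238 (0.0177 to 0.348 over pairs of libraries, and -0.0570 to 0.0525 in 1000 circular shifts of 1 change along the genome). A replacement place by place had been predicted to give a negative value, and the value was positive at this scale. The correlation of the 2 levels fell from 0.387 to 0.0311 over the same step. A property of the places that moves all marks may explain the positive value, since the H3 change correlated with the H3K27me3 change at 0.173 and with the H3K9me2 change at 0.380, but over pairs of libraries the former ran from -0.0238 to 0.364. Such a property could also hide a negative relation, and the correlation was not adjusted for H3, so a replacement is not excluded. A property of the places and a joint biological change of both marks cannot be told apart.

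EGFP-BLIMP1 positions of both days lay on chromosome X in 5.81% of cases, and those of d6PGCLC alone in 1.02%. Multi-copy sequence on X may give positions on both days, and although 3.95% of the X positions of both days lay in windows with a mean H3 signal of 1.5 or more, against 3.73% on autosomes, this does not exclude it, since H3 stood near 1 on X (0.979 to 1.03) and Y (0.937 to 1.19) alike and so may not follow copy number. A few dense clusters do not account for the X positions, since 16.1% of them lay in 100-kb bins with 3 or more, which is more than the 5.24% on autosomes but leaves most outside such bins. A single copy of X in the cells may leave weak sites there below the detection threshold of the authors' peak calls, and a true difference in binding may do so as well. Neither was tested, since the lists hold no heights. The 6096 identical bases argue against separate calls of the 2 days, so the split into both days and 1 day probably does not compare independent lists. How this bears on the share on X was not tested.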

How the results depend on the processing

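Among the alternatives of this part, division by the library mean, identical positions, set tests with a library left out, other levels for high H3K27me3 and windows as listed were chosen after the data were seen.

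Scaling turned the majority direction of several counts. With each library centred on its median, H3K27me3 gave 6258 windows for EpiLC against ESC, 42880 for d2LIF_Ag against EpiLC and 52508 for d6PGCLC against d2PGCLC (the last 2 with the majority turned), 28056 for d6PGCLC against ESC, and 64786 for d2PGCLC against EpiLC, also with the majority turned. H3K9me2 gave 8673, 9458 and 53065 bins for EpiLC against ESC, d6PGCLC against d2PGCLC and d6PGCLC against ESC, each with the majority turned. Divided by the library mean, H3K27me3 gave 3118 windows for EpiLC against ESC, 37751 and 54280 for d2LIF_Ag and d2PGCLC against EpiLC and 57553 for d6PGCLC against d2PGCLC (these 3 turned), and 30953 for d6PGCLC against ESC. H3K9me2 then gave 60 bins for EpiLC against ESC and 19547 for d6PGCLC against d2PGCLC (both turned), 4603 for d2PGCLC against EpiLC and 40531 for d6PGCLC against ESC, and H3 gave 127 for d2PGCLC against EpiLC. From d2PGCLC to d6PGCLC H3K9me2 at H3K4me3 positions and at H3K27ac positions near them turned to -0.26 in both.

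The number of windows follows the filter by construction. Without a filter, H3K27me3 gave 1031466 windows for EpiLC against ESC, 931443 and 952333 for d2LIF_Ag and d2PGCLC against EpiLC, 1091964 for d6PGCLC against d2PGCLC and 862380 for d6PGCLC against ESC. In the top 5% of windows the numbers were 62059, 43051, 37686, 49941 and 50635. The windows offset by 1 kb gave similar counts in 6 of 6 comparisons. In 100-kb bins H3K9me2 gave 18961 for EpiLC against ESC, 24760 for d6PGCLC against d2PGCLC and 24269 for d6PGCLC against ESC, and limma called 0 for d2PGCLC against EpiLC, with 6485 at an unadjusted p under 0.05. In single 2-kb windows it gave 391502, 1134816, 1081704 and, for d2PGCLC against EpiLC, 59119. H3 in 100-kb bins gave 1034 for EpiLC against ESC, 2589 for d2PGCLC against EpiLC, 1215 for d6PGCLC against d2PGCLC and 4348 for d6PGCLC against ESC (turned), and in single windows 315 (turned), 318, 335 and 275. The cause of the differences between bin sizes was not tested. In the top 10% of windows, 12 rather than 29 of 36 H3K9me2 set tests passed, and the difference at EGFP-BLIMP1 positions of d6PGCLC alone between d6PGCLC and ESC turned to -0.11.

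With the median of non-zero values as pseudocount, H3K27me3 gave 2707 windows for d2PGCLC against d2LIF_Ag, and H3 gave 126 bins for d2PGCLC against EpiLC. With an estimated correlation, 0 of 54 H3K27me3 and 0 of 36 H3K9me2 camera tests passed, where 5 and 8 had an unadjusted p under 0.05. With windows as listed, 27 rather than 29 H3K9me2 set tests passed.

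Single libraries mattered most for small changes. With 1 library left out, H3K27me3 gave 122686 to 123386 windows for EpiLC against ESC, 80039 to 95143 and 69993 to 85808 for d2LIF_Ag and d2PGCLC against EpiLC, 99848 to 104968 for d6PGCLC against d2PGCLC and 91620 to 102062 for d6PGCLC against ESC. For d2PGCLC against d2LIF_Ag it gave 818 to 4000 windows, with 818 without d2PGCLC replicate 1, 2541 without d2LIF_Ag replicate 2 and 2675 without d2PGCLC replicate 2. H3K9me2 gave 76544 to 86495 bins for EpiLC against ESC, 119071 to 124132 for d6PGCLC against d2PGCLC and 114047 to 118200 for d6PGCLC against ESC. For d2PGCLC against EpiLC it gave 3 without d2PGCLC replicate 1 and 2 without d2PGCLC replicate 2 (both turned), 1509 without EpiLC replicate 1 and 17580 without EpiLC replicate 2. H3 gave 104 without ESC replicate 1 and 30, 52 and 64 (turned) without ESC replicate 2, EpiLC replicate 1 and EpiLC replicate 2 for EpiLC against ESC, and 35, 37 and 44 without EpiLC replicate 1, d2PGCLC replicate 1 and d2PGCLC replicate 2 for d2PGCLC against EpiLC. It gave 31 to 109 for d6PGCLC against d2PGCLC, with 109 without d6PGCLC replicate 2, and 32 and 160 without ESC replicate 2 and d6PGCLC replicate 1, and 446 and 842 (turned) without ESC replicate 1 and d6PGCLC replicate 2, for d6PGCLC against ESC. Calls of named regions were lost in 28 of 144 such fits for H3K27me3, 60 of 96 for H3K9me2 and 36 of 40 for H3. Other settings ended calls of named H3K9me2 regions in 14 of 24 relative to H3, 13 of 24 after division by the mean, 8 of 24 after centring and 7 of 24 with the other pseudocount, while the counts of H3K9me2 bins relative to H3 stayed within 1.5 times in 4 of 4 comparisons. For named H3K27me3 regions this was 3 of 36 after division by the mean, 4 of 36 after centring and 0 of 36 with the other pseudocount, and for H3 1 of 10 with the other pseudocount. Set tests lost their call in 5 of 540 fits for H3K27me3 and 17 of 288 for H3K9me2.

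As a replicate block, the replicate number left the counts of H3K27me3 and H3K9me2 within 1.5 times in 6 of 6 and 4 of 4 comparisons, ended calls of named regions in 3 of 36, 6 of 24 and 2 of 10 for H3K27me3, H3K9me2 and H3, and gave 119 H3 bins for d2PGCLC against EpiLC and 59 for d6PGCLC against d2PGCLC. The labels do not say that equal numbers pair samples, and the differences between replicates 1 and 2 correlated between pairs of cell types at -0.154 to 0.114 for H3K27me3. For H3K9me2 the correlation was 0.649 between ESC and EpiLC, 0.236 between EpiLC and d2PGCLC and 0.190 between ESC and d2PGCLC, so these 3 shared part of their replicate difference, and -0.252 to -0.101 with d6PGCLC. None of the regions that lost their call with the block is named in the results.

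At 500 bp, EGFP-BLIMP1 positions of d2PGCLC lay near H3K27ac in 31.2% and near H3K4me3 in 10.3% of cases, those of d6PGCLC in 27.5% and 9.35%, H3K27ac near H3K4me3 in 16.9% and H3K4me3 near H3K27ac in 36.4%. At identical positions the shares were 0.0842%, 0.0562%, 0.0624%, 0.0356%, 0.0363% and 0.0781%. A shorter distance lowers the share by construction.

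The median of H3 on autosomes was 0.994 in ESC, 0.99 in d2PGCLC and 0.993 in d6PGCLC, and that of H3K27me3 in d2PGCLC was 0.0844. In windows without listed positions, H3 was 0.997, 0.991 and 0.998, H3K27me3 in d2PGCLC was 0.0853, and H3K9me2 was 1.10 in ESC, 0.716 in EpiLC and 0.686 in d2PGCLC. For H3K27me3 the shifts are small beside the differences between cell types, and for H3K9me2 beside all but that between EpiLC and d2PGCLC. For H3 they are of similar size to those differences. Its median over all windows was 0.992 in ESC, 0.9885 in d2PGCLC and 0.9915 in d6PGCLC. Gene-level alternatives, lists of peaks split by score and tests on counts were not run.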

Other observations

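The comparisons in this part were chosen after the data were seen, and none of them was tested.

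Across 25380 bins of 100 kb, the Spearman correlation of H3K27me3 and H3K9me2 signal was 0.469 in ESC (0.388 to 0.540 over the 4 pairs of libraries), 0.639 in EpiLC (0.550 to 0.662), 0.387 in d2PGCLC (0.249 to 0.490) and 0.0311 in d6PGCLC (-0.125 to 0.197). Neighbouring bins are not independent, so no p is given, but the range of d6PGCLC lay below those of the other 3 cell types. H3K27me3 correlated with total H3 as well, over pairs of libraries at 0.210 to 0.342 in ESC, 0.265 to 0.343 in EpiLC, 0.401 to 0.492 in d2PGCLC and 0.415 to 0.489 in d6PGCLC, so in d2PGCLC a value like that with H3K9me2 was not special to the 2 marks. The lower correlation of the levels in d6PGCLC does not show that 1 mark replaced the other place by place, since their changes from d2PGCLC, tested in an earlier part, correlated at 0.238.

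Chromosomes differed in how much H3K27me3 they held on day 2. Relative to the library mean, chromosome 11 stood at 1.12 ± 0.0252 in ESC, 1.09 ± 0.0405 in EpiLC, 1.31 ± 0.0664 in d2LIF_Ag, 1.35 ± 0.0152 in d2PGCLC and 1.22 ± 0.0306 in d6PGCLC, and chromosome 19 at 1.13 ± 0.0185, 1.18 ± 0.0104, 1.36 ± 0.100, 1.34 ± 0.00690 and 1.26 ± 0.00606. Chromosome 3 ran the other way, with 0.897 ± 0.0256, 0.932 ± 0.0158, 0.743 ± 0.0237, 0.716 ± 0.00829 and 0.789 ± 0.0252. Signal was also more concentrated, and the 1% of windows with the highest signal held 4.32 ± 0.391% of all H3K27me3 in ESC, 4.29 ± 0.330% in EpiLC, 12.9 ± 2.34% in d2LIF_Ag, 11.3 ± 1.20% in d2PGCLC and 5.80 ± 0.716% in d6PGCLC.

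Total H3 on chromosome 8 was 1.05 ± 0.00261 times the library mean in ESC, 1.04 ± 0.00612 in EpiLC, 0.921 ± 0.0143 in d2PGCLC and 0.919 ± 0.00520 in d6PGCLC, and H3K9me2 on that chromosome was 1.04, 1.09, 0.933 and 0.857. H3 also shifted on chromosome 6 (1.12 ± 0.00341, 1.09 ± 0.00898, 1.03 ± 0.00233 and 1.00 ± 0.0110) and chromosome 16 (1.23 ± 0.00500, 1.24 ± 0.00266, 1.32 ± 0.0109 and 1.34 ± 0.00111). Whether the copy number of these chromosomes differed between the cultures was not tested.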
